A study of Mus musculus with 9 samples.

How the data were processed

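Gene expression was measured by poly(A) RNA sequencing of mouse oocytes in 9 libraries, 3 for each of 3 groups. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected on oligo(dT) beads, and the fragmented mRNA was made into strand-marked cDNA libraries by the dUTP method and amplified by PCR. Selection on poly(A) means that a transcript with a shorter tail can be recovered less well, and PCR copies were not told apart by molecular identifiers. The submitters' processing notes name cutadapt 1.9 for trimming of reads, HISAT2 2.0.4, StringTie 1.3.4d and the mouse genome build GRCm38. The counting tool, its strand setting and the annotation release are not given in the sources used here.

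The authors deposited 1 table of 26358 genes with an FPKM column and a raw count column for each library. The deposited counts are whole numbers of reads per gene that were not normalized. The deposited FPKM values are, by a check on the table, the count divided by gene length and by 1 factor per library. Across genes, the ratio of count to FPKM against that of fresh replicate 1 had an SD of 0.00102 to 0.00134 (log2) for the other libraries. Every value column matched the labels of 1 sample. Of the gene identifiers, 26286 were found in a reference gene table of the same build, and 25498 had the same symbol there. Positions were taken from the deposited table. Lengths and GC contents were those of each gene's longest protein-coding transcript, or else its longest transcript, in GENCODE sequences of that build. There were 41 symbols shared by 84 entries of the table. Because the strand setting is not given, reads of a gene and an antisense or overlapping neighbour cannot be told apart. Levels of ribosomal protein genes, tubulins, Ndufb4 and the Dynlt1 copies are uncertain, since reads can be shared with near-identical copies or processed pseudogenes.

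Groups were taken from the treatment labels. The labels do not say that replicates came from separate animals or pools of oocytes, so p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise. The chi-square per degree of freedom of their counts lay between 85.8 and 326. Total counts lay between 49337232 and 80877288 per library. A count of 0 allows a level of up to 3 counts, which is 0.0371 to 0.0608 CPM (counts scaled to library size) depending on the library, and this covers counting error only.

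The plan set limma on log2(FPKM + 1) as the main test unless the table also held counts, in which case edgeR's quasi-likelihood test on the counts was to be used. The table held counts, so edgeR was used and limma became the alternative. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17545 genes. Library sizes were scaled by TMM. All 9 libraries entered 1 fit with 1 coefficient per group, and 3 contrasts and an F test over all groups were taken from it. P-values were adjusted by the method of Benjamini and Hochberg within each contrast, and a gene was called changed at an adjusted p under 0.05 with no minimum fold. The common biological coefficient of variation was 0.662. Log2 fold changes carry the standard error (SE) of the fit, and levels are given as TMM-scaled CPM with the SD over 3 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

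The test was checked on counts simulated from the real means and library sizes with 200 genes changed among 17545. In simulated comparisons of cryopreservation-2 with fresh, 78.3% of 4-fold changes and 12% of 2-fold changes were called among genes above 5 CPM, with a mean of 5 false calls over 3 runs. In simulated comparisons of cryopreservation-1 with fresh, the shares were 79% and 11.3%, with a mean of 1.33 false calls.

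The groups, the comparisons, the tests, the rule for named genes, 32 gene lists and most of the alternatives were chosen before the data were examined. The lists, written from general knowledge of oocytes and cryoinjury, cover oocyte maternal identity, cumulus and granulosa cell markers, immune and blood cell markers, stromal and endothelial cell markers, heat shock proteins, cold-inducible proteins, the unfolded protein response, antioxidant defence, iron handling, osmotic response and water channels, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, mitochondrial dynamics, glycolysis and the tricarboxylic acid cycle, lipid droplets and fatty acids, cholesterol synthesis, apoptosis, autophagy and lysosome, DNA damage response, meiotic spindle, cell cycle control of maturation, actin cytoskeleton, calcium signalling and egg activation, DNA methylation and histone modification, maternal mRNA storage and decay, zygotic genome activation, immediate early genes, interferon response, proteasome, cytosolic ribosomal proteins, mitochondrial ribosomal proteins and histones. Each list with at least 5 tested members, 31 of them, was tested with limma's camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and adjusted over the 31 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, 0 lists passed in any of the 3 comparisons, so camera's list calls hold only under the preset one. Fry does not compare a list with other genes. It gave adjusted p of 0.0185 to 0.0329 for the 5 lists called in cryopreservation-2 against fresh. Between the methods it gave 0.0345 to 0.0372 for oxidative phosphorylation, cytosolic ribosomal proteins, cell cycle control and cholesterol synthesis. There the proteasome (0.06) and mitochondrial ribosomal proteins (0.134) did not pass fry. In cryopreservation-1 against fresh 0 lists passed fry. For some lists that did not pass camera at the preset correlation, the median, the mean and camera's direction differed in sign. These were, against fresh in cryopreservation-2, the lists of oocyte identity, stromal cells, heat shock, iron, mitochondrial dynamics and calcium signalling, and in cryopreservation-1 those of cumulus cells, the unfolded protein response, iron, apoptosis, autophagy, DNA damage, cell cycle and histones. Between the methods they were those of heat shock, mitochondrial dynamics, lipids, spindle and interferon.

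Genes were named by a fixed rule. It takes the 8 largest changes in each direction among called genes with no overlap between the groups' libraries and a mean FPKM of at least 5 in the higher group, without clone-numbered genes. It adds up to 3 called members of each list by adjusted p and 15 genes named whatever their value. Where too few genes passed, it takes the 5 smallest unadjusted p-values in each direction. Genes named in the text outside this rule are said to be so. Library structure was described on log2(FPKM + 1) of 8934 genes with a mean FPKM of at least 1, and differences of library measures between groups were tested by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. The likeness of the 2 methods' changes was set against 50 simulations of unchanged groups that share the fresh libraries, and the overlap of the 2 comparisons of cryopreservation-2 against 50 that share its libraries. Gene Ontology terms of the deposited table were tested by one-sided Fisher's exact tests against the tested genes with terms.

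The alternatives tried were RLE scaling, DESeq2, no low-count filter, robust dispersions, a replicate block, fits of 2 groups alone, limma on FPKM with other pseudocounts, filters, scalings and weights, and leaving out each library in turn. Thinning to the smallest library, a correction for GC content and transcript length, protein-coding genes alone, upper-quartile scaling and a minimum mean FPKM of 1 in edgeR were added after the data were seen. Reads were not analysed here, so transcript isoforms, poly(A) tail lengths and intronic reads were not examined.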

Results

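Poly(A) RNA was sequenced from mouse oocytes that were fresh or had been cryopreserved by 1 of 2 methods, with 3 libraries per group. In the first method, here cryopreservation-1, oocytes were frozen on a cryotop, a thin strip that carries a very small volume, in sucrose at 0.5 M with EG and DMSO at 15% each. In the second, cryopreservation-2, they were frozen in a straw with trehalose at 1 M, EG at 17.5% and nanoparticles that the labels call PVA/Fe3O4/GO. Carrier, solutes and nanoparticles differed together between the methods, so the design compares whole protocols. The total count per library averaged 78010000 ± 3559000 in fresh, 75070000 ± 9355000 in cryopreservation-1 and 50490000 ± 1044000 in cryopreservation-2 (SD, n = 3 each). All 3 cryopreservation-2 libraries were smaller than the other 6 (exact permutation p = 0.1 against each group, the smallest this design allows). Between 14751 and 16788 genes had at least 10 counts per library.

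The libraries carried an oocyte profile in all groups. Genes of oocyte identity, among them Gdf9 and Bmp15, the growth factors that oocytes send to surrounding follicle cells, took 7.32% to 9.71% of the counts of each library. Bmp15 stood at 990 ± 66.5, 897 ± 201 and 951 ± 237 CPM in fresh, cryopreservation-1 and cryopreservation-2 (SD, n = 3). Markers of cumulus and granulosa cells, the somatic cells around the oocyte, took 0.0953% to 0.177% of counts, most of it from Serpine2 at 1067, 1074 and 1464 CPM in the 3 groups. Immune and blood markers took at most 0.00173%, led by C1qb and Cd68, and stromal and endothelial markers at most 0.0220%, led by Pecam1 and Myh11. Serpine2, C1qb, Cd68 and Pecam1 lie outside the naming rule and were chosen after their values were seen, as the highest of their lists. Ptx3, Col1a1 and Ptprc, markers of cumulus, stromal and blood cells, had between 0 and 14 counts in every library. Of 12 cumulus and granulosa and 4 immune and blood markers tested, 0 were called in any of the 3 comparisons by edgeR, and also 0 adjusted over the list alone. Of 10 stromal and endothelial markers tested, Krt8 and Myh11 were called higher in cryopreservation-2 than in fresh. Over all genes, 0 of these 10 were called in cryopreservation-1 against fresh or between the methods.

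Cryopreservation-2 libraries stood apart from the other 6. Across 8934 genes, the first principal component held 45.7% of the variance and placed them between 36.3 and 40.7, against -28.5 to -10.7 for fresh and cryopreservation-1 libraries together. The mean Pearson correlation across genes was 0.965 between fresh and cryopreservation-1 libraries, against 0.961 within fresh and 0.972 within cryopreservation-1. It was 0.911 between fresh and cryopreservation-2 and 0.920 between cryopreservation-1 and cryopreservation-2, against 0.953 within cryopreservation-2. Genes are not independent replicates, so these correlations are descriptions. The second component, 20.2% of the variance, set cryopreservation-2 replicate 1 (-37.9), fresh replicate 3 (-19.6) and cryopreservation-1 replicate 3 (-16.5) apart from the rest of their groups. In the same order, these libraries had 8667, 9108 and 8421 genes at 0 counts, against at most 7744 in the others. They also had the fewest genes with at least 10 counts.

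**Figure D1:**
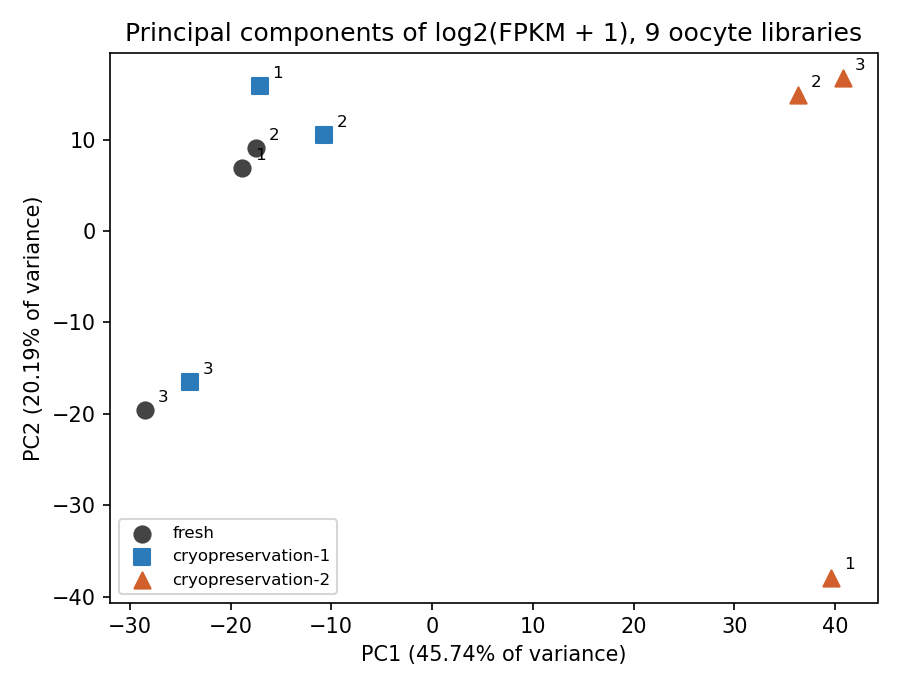
Scores of the 9 libraries on the first (horizontal) and second (vertical) principal component of log2(FPKM + 1), with the percent of variance on each axis. Each point is 1 library with its replicate number, coloured by group. The 3 cryopreservation-2 libraries lie at 36.3 or higher on the first component and the other 6 at -10.7 or lower.

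The comparison of cryopreservation-1 with fresh asks how oocytes frozen on a cryotop differ from unfrozen ones. No single gene passed the test. Among genes with no overlap between the groups' libraries and a mean FPKM of at least 5 in the higher group, the smallest unadjusted p-values for lower values were those of Smarca5, the ATPase of ISWI chromatin remodelling complexes, at 48.9 ± 7.90 against 120 ± 47.9 CPM (SD, n = 3), Rac1, a small GTPase of the actin cytoskeleton, at 111 ± 9.53 against 341 ± 216 CPM, and Rnf139, Trim59 and Clptm1l. For higher values they were those of Klhl25, at a log2 fold change of 0.97 (SE 0.23), of Arpc3, a subunit of the actin-nucleating complex, at 68.0 ± 6.99 against 38.4 ± 3.40 CPM, and of Ctnnbl1, Snrnp70 and Supt5. All 10 had an adjusted p of 1. EdgeR called 0 of 17545 genes, with 828 at an unadjusted p under 0.05, which is 4.72% of the genes, and the smallest adjusted p was 0.337. DESeq2 called 43 genes and limma on FPKM 0. In simulated data of the same design, 79% of 4-fold but 11.3% of 2-fold changes were found, so changes near 2-fold were mostly not detectable.

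The list of mitochondrial genome transcripts was called lower in cryopreservation-1, but only at the preset correlation. All 13 protein-coding genes of the mitochondrial genome, which encode core subunits of the respiratory chain, had a negative log2 fold change, with a median of -0.52 and quartiles of -0.57 and -0.46. Camera gave an adjusted p of 1.35e-07 for the list at the preset correlation of 0.01. With the estimated correlation, which was 0.626, camera gave an adjusted p = 0.678, and fry gave an adjusted p = 0.627. The lowest was mt-Nd6 at -0.89 (SE 0.42) and the highest mt-Co3 at -0.23 (SE 0.24), both named after their values were seen, and 0 of the 13 passed singly, either over all genes or adjusted over the list alone. Mitochondrial genes took 0.529 ± 0.0629% of counts in cryopreservation-1 and 0.671 ± 0.0921% in fresh (SD, n = 3, exact permutation p = 0.2). The list of nuclear genes of the mitochondrial ribosome was called higher at the preset correlation, with a median of 0.24 over 76 members (camera adjusted p = 0.00546). With an estimated correlation camera gave an adjusted p = 0.678 for it. Of its members, 0 were called over all genes and 0 adjusted over the list alone. That second call was lost without fresh replicate 1 (adjusted p = 0.102), without fresh replicate 3 (0.363), without cryopreservation-1 replicate 2 (0.508) and after a correction for GC content and length (0.083), over a range of adjusted p of 2.6e-06 to 0.508.

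The other lists did not pass in cryopreservation-1, with adjusted p between 0.0752 and 0.873, and 0 of their members were called over all genes. Adjusted over the list alone, 1 member each was called higher in the stromal and endothelial, unfolded protein response and immediate early lists, and 1 higher and 1 lower in the actin list. Heat shock proteins had a median log2 fold change of 0.03 over 17 members, cold-inducible proteins -0.10 over 9 and antioxidant genes 0.13 over 29. Of single genes, Cirbp and Rbm3, RNA-binding proteins induced by mild cold, had log2 fold changes of 0.26 (SE 0.22) and 0.05 (SE 0.27), and Sod1, the cytosolic superoxide dismutase, 0.19 (SE 0.24), all with an edgeR adjusted p of 1.

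The comparison of cryopreservation-2 with fresh asks the same of oocytes frozen in a straw with nanoparticles. Lists of genes of protein synthesis, respiration and protein breakdown were called higher at the preset correlation, while Arid5b, Dazl and Aqp9 fell. With an estimated correlation these lists did not pass (adjusted p = 0.401 to 0.558). Arid5b, a DNA-binding partner of a histone demethylase (ENSMUSG00000019947, chromosome 10, 68092520 to 68278740 on the minus strand of GRCm38), was 36.1-fold lower, at 4.90 ± 0.688 against 177 ± 95.9 CPM (SD, n = 3, edgeR adjusted p = 0.00166). Mrps33, a protein of the mitochondrial ribosome (ENSMUSG00000029918, chromosome 6, 39801804 to 39810988, minus strand), was 3.98-fold higher, at 173 ± 4.70 against 43.5 ± 6.47 CPM (adjusted p = 0.00482). Hspa8, the constitutive heat shock cognate chaperone (ENSMUSG00000015656, chromosome 9, 40800984 to 40810087, plus strand), was 5.98-fold higher, at 163 ± 55.3 against 27.2 ± 4.30 CPM (adjusted p = 0.00438). Dazl, an RNA-binding regulator of translation in germ cells (ENSMUSG00000010592, chromosome 17, 50279395 to 50293636, minus strand), was 3.31-fold lower, at 479 ± 36.8 against 1587 ± 548 CPM (adjusted p = 0.00611).

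In all, edgeR called 944 of 17545 genes between cryopreservation-2 and fresh, 558 higher and 386 lower, and 786 of them changed at least 2-fold. DESeq2 called 2447, limma on FPKM 1688 and edgeR on these 2 groups alone 429. The share of higher calls was 59.1%. It was 74.0% with limma on FPKM and 44.9% of 1491 calls after a correction for GC content and transcript length, so the balance of directions depends on the processing. The count fell to 398, 594 and 231 without fresh replicates 1, 2 and 3, to 491 and 511 without cryopreservation-1 replicates 1 and 2, and to 365 and 282 without cryopreservation-2 replicates 2 and 3. Without cryopreservation-2 replicate 1, which stood apart on the second component, it was 786.

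Nuclear-encoded genes of oxidative phosphorylation rose, with a positive change in 67 of 75 members and a median log2 fold change of 1.38 (camera adjusted p = 6.81e-18, adjusted p = 0.401 with an estimated correlation). Of these, 26 were called higher and 0 lower over all genes, and 44 higher and 1 lower adjusted over the list alone. Ndufa1, Ndufb4 and Ndufs5, all subunits of complex I, rose by 3.27 (SE 0.45), 3.41 (SE 0.42) and 2.27 (SE 0.30) on the log2 scale, and Ndufb11 rose 5.66-fold. The 13 genes of the mitochondrial genome did not pass (median -0.41, camera adjusted p = 0.0712), with 0 called over all genes and 0 adjusted over the list alone. Among genes of mitochondrial dynamics, the outer membrane channel Vdac3 and the fission factors Mff and Fis1 rose 3.28-fold, 3.36-fold and 2.22-fold, and of 24 members 4 were called higher and 2 lower, with 5 and 3 adjusted over the list alone. Of 33 genes of glycolysis and the tricarboxylic acid cycle, 3 were called, all higher, namely Pdhb of pyruvate dehydrogenase at 2.49-fold, the fumarase Fh1 at 2.60-fold and the lactate dehydrogenase Ldhb at 2.53-fold (5 higher and 2 lower adjusted over the list alone).

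Cytosolic ribosomal proteins rose as a group, with a positive change in 63 of 72 members and a median of 1.62 on the log2 scale (camera adjusted p = 3.25e-13, adjusted p = 0.401 with an estimated correlation). Over all genes 18 were called, all higher, and 27 adjusted over the list alone. Rpl4 rose from 39.3 ± 4.85 to 112 ± 18.4 CPM and Rplp0 from 37.1 ± 4.01 to 96.2 ± 7.67 CPM (SD, n = 3), levels that can include reads of processed pseudogenes. Their summed share of counts was 0.144 ± 0.0231% in cryopreservation-2 and 0.0784 ± 0.0145% in fresh (exact permutation p = 0.1). Mitochondrial ribosomal proteins rose by a median of 0.74 over 76 members (camera adjusted p = 3.31e-09, adjusted p = 0.558 with an estimated correlation), with 16 called higher and 1 lower, and 29 and 3 adjusted over the list alone. Mrps31 rose 7.12-fold and Mrps28 4.63-fold. Proteasome genes rose by a median of 0.67 over 38 members (camera adjusted p = 2.28e-06, adjusted p = 0.506 with an estimated correlation), with 9 called higher and 0 lower, and 16 and 2 adjusted over the list alone. Psma6, Psmb2 and Psmb5, of the catalytic core particle, rose 3.71-fold, 4.10-fold and 5.16-fold. Transcripts of called higher genes had a median length of 1588 bases, against 3028 for called lower genes and 2548 for all tested genes.

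**Figure D2:**
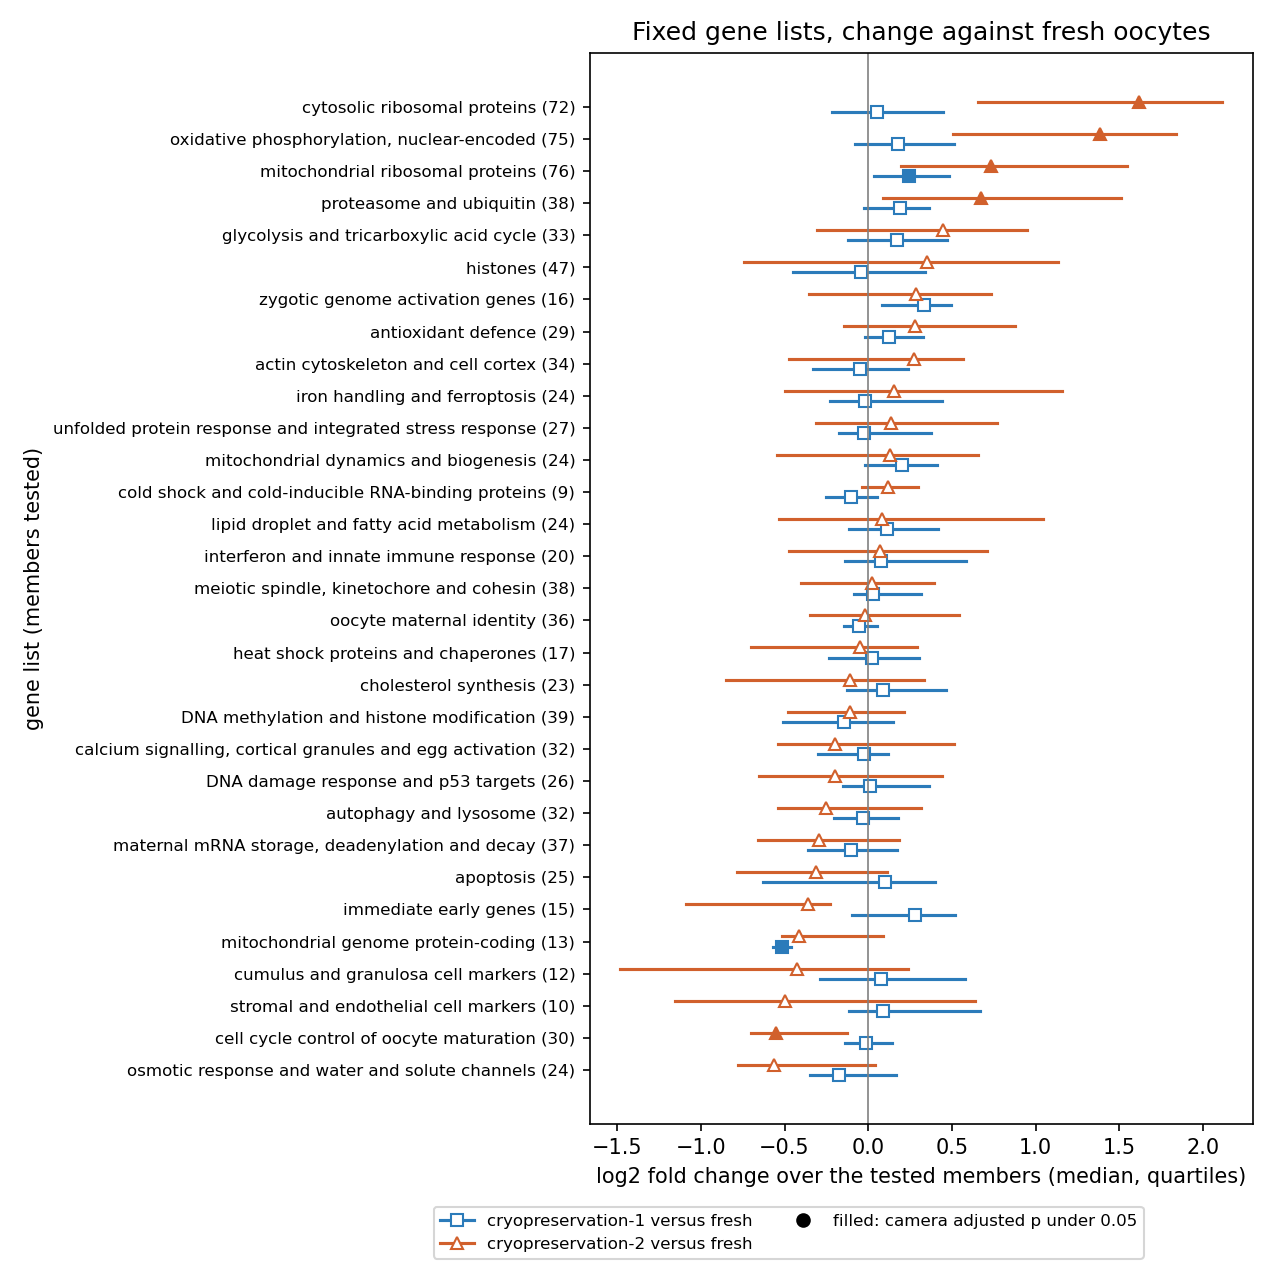
Median log2 fold change against fresh (horizontal axis) of 31 gene lists (vertical axis, tested members in parentheses), with lines from the lower to the upper quartile of the members. Squares stand for cryopreservation-1 and triangles for cryopreservation-2, and filled symbols had a camera adjusted p under 0.05 at the preset correlation of 0.01. The ribosomal list reaches 1.62 in cryopreservation-2 and 0.05 in cryopreservation-1.

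Cell cycle regulators of oocyte maturation fell as a group in cryopreservation-2, with a median of -0.55 over 30 members (camera adjusted p = 0.00375, adjusted p = 0.401 with an estimated correlation). Over all genes 1 was called lower and 1 higher, and 4 lower and 1 higher adjusted over the list alone. The call was lost with limma on FPKM under quantile normalization or a minimum mean FPKM of 5, over a range of adjusted p of 3.37e-04 to 0.102. Cdk2, a cyclin-dependent kinase, fell by 1.99 (SE 0.31) on the log2 scale, and Pabpn1l, a poly(A)-binding protein of oocytes that takes part in maternal mRNA decay, rose by 1.32 (SE 0.27). Of 37 genes of maternal mRNA storage and decay 2 were called higher and 1 lower, with 3 and 8 adjusted over the list alone. The deadenylases Parn and Pan2 changed in opposite directions, 3.01-fold higher and 1.73-fold lower. Of 38 spindle and kinetochore genes 3 were called, all higher (5 higher and 2 lower adjusted over the list alone). These were Birc5, of the chromosomal passenger complex, at 2.77-fold, the checkpoint gene Bub3 at 2.20-fold, and Tubb5 at 2.90-fold. Among 34 actin genes, Arpc3, Tmsb10 and Actg1 rose 2.60-fold, 5.38-fold and 2.74-fold, and 5 were called higher and 1 lower (5 and 2 adjusted over the list alone).

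Antioxidant genes did not pass as a list (camera adjusted p = 0.0712), but 5 of 29 members were called, all higher, and 5 adjusted over the list alone. Sod1 (ENSMUSG00000022982, chromosome 16, 90220754 to 90226329, plus strand) rose 3.54-fold, to 138 ± 25.3 from 38.9 ± 5.02 CPM (SD, n = 3, edgeR adjusted p = 0.00611). Txn1, a thioredoxin, rose 3.76-fold and the peroxiredoxin Prdx5 2.26-fold. Gpx4, which reduces lipid peroxides, had a log2 fold change of 1.35 (SE 0.55, adjusted p = 0.186) and did not pass. Of 24 iron genes, the ferritin light chain gene Ftl1 rose 3.18-fold and Slc3a2, a subunit of the cystine transporter, fell 1.76-fold, and 1 was called in each direction also adjusted over the list alone. Fth1 and Tfrc did not pass, at -0.52 (SE 0.31) and -2.34 (SE 1.12). Beside the rise of Hspa8, the heat shock transcription factor Hsf1 and the co-chaperone Dnajb1 fell 1.87-fold and 1.93-fold, out of 17 heat shock genes with 1 called higher and 2 lower (2 and 3 adjusted over the list alone). The heat-inducible Hspa1a had 15 to 66 counts in cryopreservation-2 and 0 to 74 in fresh, with an adjusted p of 0.828. Of the unfolded protein response 3 of 27 genes were called, all higher (4 adjusted over the list alone), namely Creld2 at 2.59-fold, Manf at 3.19-fold, both proteins of endoplasmic reticulum stress, and Atf3. Atf3, a stress-induced transcription factor, had 0 counts in all 3 fresh libraries and 115 counts over the cryopreservation-2 group, which is at least 59.2-fold higher against a floor of 3 counts over the group. In the cryopreservation-1 libraries it had 37, 61 and 12 counts, so its presence was not particular to cryopreservation-2.

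Aqp9, a channel for water and glycerol (ENSMUSG00000032204, chromosome 9, 71110659 to 71168657, minus strand), fell 2.54-fold, from 71.0 ± 12.6 to 28.0 ± 2.41 CPM (SD, n = 3, edgeR adjusted p = 0.00969). It was the 1 member called among 24 genes of osmotic response and water channels, over all genes and adjusted over the list alone (camera adjusted p = 0.0771). Aqp3 had 0 counts in cryopreservation-2 and 0 to 16 in fresh libraries and was below the filter. Of 23 genes of cholesterol synthesis and its control 2 fell, Insig1 1.98-fold and Idi1 2.62-fold (2 adjusted over the list alone). Of 36 oocyte identity genes 3 were called higher and 2 lower (5 and 2 adjusted over the list alone), among them Uchl1, a ubiquitin hydrolase, at 2.58-fold and Padi6, a component of cytoplasmic lattices, at 2.15-fold. Zp3, a zona pellucida protein, Gdf9 and Bmp15 had log2 fold changes of 0.31 (SE 0.38), -0.34 (SE 0.29) and -0.06 (SE 0.23), and Cirbp, Rbm3 and the DNA methyltransferase gene Dnmt1 had 0.30 (SE 0.22), -0.02 (SE 0.27) and 0.18 (SE 0.27), none of which passed. The histone demethylase genes Kdm1b and Kdm4a fell 2.13-fold and 1.81-fold, the 2 called of 39 genes of DNA methylation and histone modification (2 lower and 1 higher adjusted over the list alone).

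Among the remaining lists, Wipi1 and Ulk2 of autophagy fell 2.77-fold each, the 2 called of 32 (2 adjusted over the list alone). Calm2, a calmodulin gene, rose 4.34-fold beside Padi6, the 2 called of 32 genes of calcium signalling and egg activation (2 adjusted over the list alone). The immediate early gene Klf6 fell 3.78-fold while Atf3 rose, the 2 called of 15, and the interferon-induced Ifit1 rose 6.44-fold, the 1 called of 20, with the same counts adjusted over the list alone. Birc5 was the 1 called of 25 apoptosis genes (1 higher and 2 lower adjusted over the list alone), and the histone gene H3f3a, at 2.52-fold, the 1 called of 47 (1 adjusted over the list alone). Of 10 stromal and endothelial markers 2 were called higher, over all genes and adjusted over the list alone. These were Myh11, a smooth muscle myosin, at 36.3 ± 2.09 against 19.7 ± 2.61 CPM, and Krt8, a keratin of simple epithelia, with 36 to 139 counts against 0 to 4. No member was called over all genes or adjusted over the list alone among 9 cold-inducible, 24 lipid droplet and fatty acid, 26 DNA damage and 16 zygotic genome activation genes. Lists other than the 5 called had camera adjusted p between 0.0712 and 0.983.

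Among called genes with no overlap between the groups' libraries and a mean FPKM of at least 5 in the higher group, clone-numbered genes left out, the largest rises outside the lists were those of Dbt, a subunit of the branched-chain alpha-keto acid dehydrogenase (ENSMUSG00000000340, chromosome 3, 116513070 to 116549981, plus strand), from 9.54 ± 2.86 to 144 ± 97.7 CPM (SD, n = 3, edgeR adjusted p = 0.00511), and of Fkbp6, Abt1, Trim15, Tm2d1 and Cdpf1, between 8.75-fold and 15.1-fold. By the same limits the largest falls of genes that are not pseudogenes, after that of Arid5b, were those of the orphan receptor Gprc5c at 14.2-fold, the tyrosine kinase Frk at 5.32-fold, Hid1 at 5.10-fold, Cd300c at 5.09-fold, the lysosomal arylsulfatase Arsb at 4.88-fold and the oxysterol hydroxylase Cyp7b1 at 4.34-fold. The pseudogene Rpsa-ps4 was 64.7-fold lower, a value that is uncertain because its reads can come from its parent gene.

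**Figure D3:**
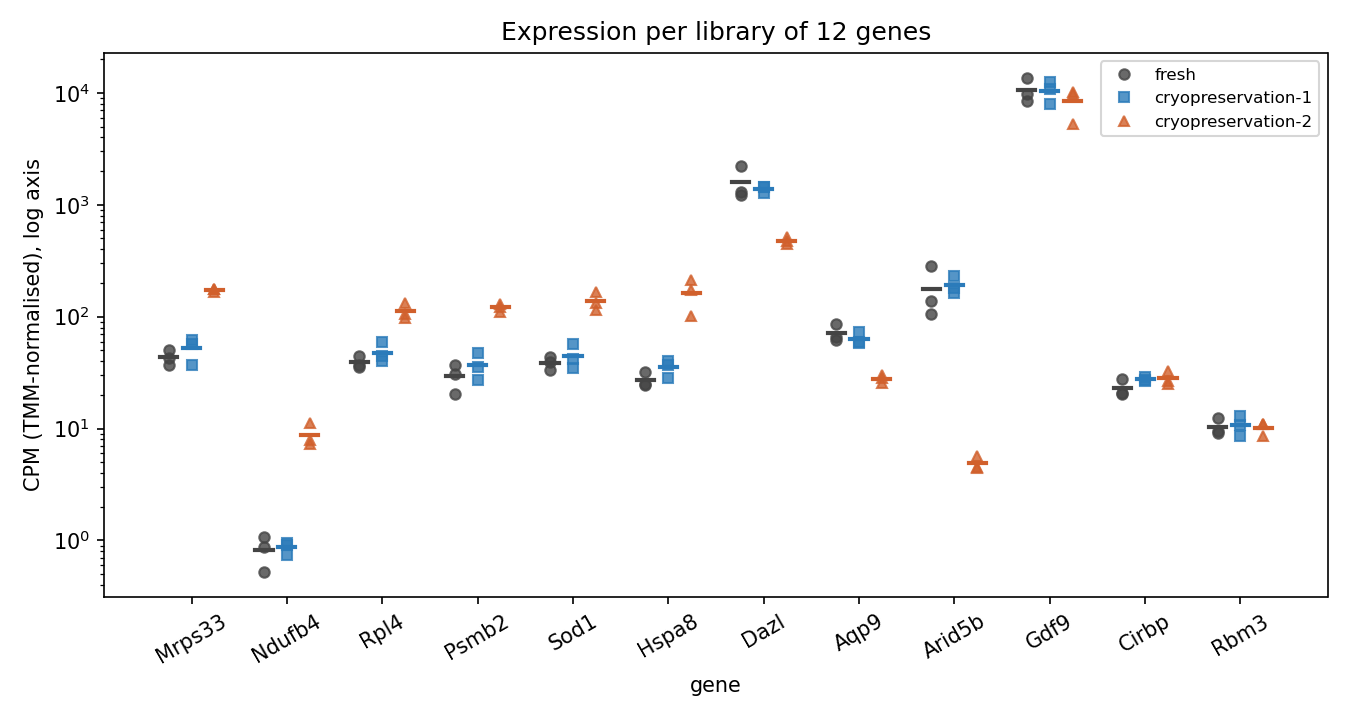
Expression of 12 genes (horizontal axis) as TMM-scaled CPM on a log axis (vertical axis). Each point is 1 library and each bar the mean of 3 libraries of a group. Dazl, Aqp9 and Arid5b are lower and Mrps33, Ndufb4, Rpl4, Psmb2, Sod1 and Hspa8 higher in all 3 cryopreservation-2 libraries than in the other 6, while Gdf9, Cirbp and Rbm3 overlap between groups.

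The comparison of cryopreservation-2 with cryopreservation-1 tests the difference between the methods itself. The same 4 groups of genes were higher in cryopreservation-2. Oxidative phosphorylation genes had a median log2 fold change of 1.08 over 75 members (camera adjusted p = 2.33e-17, adjusted p = 0.543 with an estimated correlation), with 12 called higher and 36 higher and 2 lower adjusted over the list alone. Cytosolic ribosomal proteins had a median of 1.27 (camera adjusted p = 5.92e-15, adjusted p = 0.543 with an estimated correlation), with 8 called higher and 27 adjusted over the list alone. Mitochondrial ribosomal proteins had 0.45 (camera adjusted p = 5.31e-06, adjusted p = 0.599 with an estimated correlation), with 6 called higher and 1 lower, and 15 and 2 adjusted over the list alone. Proteasome genes had 0.52 (camera adjusted p = 6.28e-05, adjusted p = 0.543 with an estimated correlation), with 5 called higher, and 10 higher and 2 lower adjusted over the list alone. The proteasome call was lost with limma on FPKM at a minimum mean of 5 (adjusted p = 0.0751, the highest of a range from 2.66e-06).

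Cell cycle regulators of maturation were lower than in cryopreservation-1, with a median of -0.40 (camera adjusted p = 0.0138, adjusted p = 0.543 with an estimated correlation). Cdk2 fell 5.35-fold and Cpeb1, a regulator of cytoplasmic polyadenylation, 1.86-fold, the 2 called of 30 (4 lower adjusted over the list alone). This call too was lost with limma on FPKM under quantile normalization or a minimum mean of 5, over a range of adjusted p of 0.00172 to 0.235. Cholesterol synthesis genes were lower by a median of -0.73 over 23 members (camera adjusted p = 0.0409, adjusted p = 0.543 with an estimated correlation), with Insig1 called, at 2.08-fold lower, over all genes and adjusted over the list alone. That call was lost in 17 of 32 alternatives, among them without cryopreservation-1 replicate 2 (adjusted p = 0.0608) and without cryopreservation-2 replicate 3 (0.148), within a range of 0.00787 to 0.406.

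Single genes between the methods included Dapk3, a death-associated protein kinase, at 23.5 ± 9.82 against 0.556 ± 0.258 CPM (SD, n = 3, edgeR adjusted p = 0.0285), and the small GTPase Arf6 at 26.0 ± 3.85 against 1.56 ± 0.369 CPM (adjusted p = 0.0296). Ppp2ca, the catalytic subunit of a major protein phosphatase, was 13.5-fold higher, and Traf3ip1 and Grsf1 12.6-fold and 10.3-fold. Rac1 was 4.46-fold higher, Lamp1, a lysosomal membrane protein, 4.03-fold and Hspa8 4.62-fold. Sod1 was 3.10-fold higher. Arid5b was 39.3-fold lower, Lrrc31 14.6-fold and Rassf3 10.7-fold. Mfn1, of mitochondrial fusion, was 2.14-fold lower, Vdac1 1.85-fold, Trp53bp1, of the DNA damage response, 2.08-fold, Kdm4a 2.40-fold, Dazl 2.89-fold, Oog1, an oocyte-specific gene, 1.80-fold and Aqp9 2.28-fold.

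EdgeR called 483 of 17545 genes between the methods, 263 higher and 220 lower in cryopreservation-2, while DESeq2 called 1868 and limma on FPKM 1271. The share of higher calls was 54.5%. It was 62.5% with limma on FPKM, 74.6% with limma without a filter, and 41.1% of 1003 calls after the correction for GC content and length. Here too the balance of directions depends on the processing. The count fell to 15, 103 and 16 without cryopreservation-1 replicates 1, 2 and 3, and to 237, 174 and 96 without cryopreservation-2 replicates 1, 2 and 3. Lists other than the 6 called had camera adjusted p between 0.0687 and 0.905. An F test over all 3 groups called 619 genes (2218 with DESeq2 and 1327 with limma on FPKM). That count was 406, 469 and 327 without fresh replicates 1, 2 and 3, 171, 288 and 269 without those of cryopreservation-1, and 319, 162 and 116 without those of cryopreservation-2, each in the same order.

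The comparisons of cryopreservation-2 with fresh and with cryopreservation-1 shared 381 called genes, all with the same direction, 199 higher and 182 lower. Independent lists of the same sizes would share 8.36 and 4.84. Both comparisons use the same cryopreservation-2 libraries, which independent lists leave out. In 50 simulations of unchanged groups that share these libraries, added after the overlap was seen, at most 2 genes were called in both. However, these simulations called a mean of 0.08 and at most 2 genes in either comparison. They could not give a larger overlap, so they do not show how much of it the shared libraries account for. Of the 944 genes called against fresh, 940 (99.6%) lay in the same direction against cryopreservation-1, but so did 87.3% (84.1% to 89.7%) of the 944 genes with the smallest p in the simulations. Part of the overlap may thus come from the shared libraries, and groups of 3 cannot be split into parts of at least 2 to test it.

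The changes of the 2 methods against fresh were also set against each other. Over 8932 genes with a mean FPKM of at least 1, the correlation across genes was 0.348 and the covariance 0.125, against 0.499 (0.470 to 0.545) and 0.103 (0.0956 to 0.119) in 50 simulations of unchanged groups that share the fresh libraries. The same sign was found for 63.8% of these genes and for 66.7% (65.3% to 67.7%) in the simulations. Over all 17545 tested genes the correlation was 0.508 against 0.496 (0.470 to 0.514), and the covariance 1.00 against 0.767 (0.716 to 0.812). The covariance thus exceeded the simulated one in both sets, by 0.022 and by 0.233, while the shares with the same sign did not. The simulations share the fresh libraries too, but they take the spread from the fitted model and draw each gene on its own. Deviations of a library that many genes share are thus left out, and the simulated ranges can be too narrow. Part of the excess may still come from the fresh libraries, which are too few to be split into parts of at least 2.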

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

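In this part, the counts of other splits of the samples, the use of the upper end of the matched sets for transcript length and the test of polyadenylated mRNAs were chosen only after the results were seen. The correction for GC content and length was revised once after its first output had been seen, because that version also moved the level of whole libraries and left a smaller share of higher calls. Several results were picked out because the change against fresh differed between the methods by a direct test of cryopreservation-2 against cryopreservation-1. These were 483 single genes and the medians of 6 gene lists, at 1.085 (log2) for oxidative phosphorylation, 1.266 for cytosolic ribosomal proteins, 0.451 for mitochondrial ribosomal proteins, 0.52 for the proteasome, -0.395 for cell cycle control of maturation and -0.726 for cholesterol synthesis. All 6 lists had an adjusted p of 0.543 or 0.599 with an estimated correlation. The single-gene count was 15, 103 and 16 without cryopreservation-1 replicates 1, 2 and 3 and 237, 174 and 96 without those of cryopreservation-2. Groups of 3 are too small for a test of single outlying samples.

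The first pattern is that 944 genes were called between cryopreservation-2 and fresh but 0 between cryopreservation-1 and fresh (828 at an unadjusted p under 0.05, 43 with DESeq2, 0 with limma on FPKM). Lower depth of the cryopreservation-2 libraries is argued against, since with every library thinned to 49337232 counts 991 genes were called, 921 of them among the 944, and 0 for cryopreservation-1. A bias that follows a smooth trend in GC content and transcript length is argued against as the source of most calls. After a correction for such a trend 88.8% of the called genes (838) were still called, although the share of higher calls went from 59.1% to 44.9%. The correction moved log2 fold changes by a median of 0.135, which is small beside the median absolute log2 fold change of 1.47 of the called genes. A bias that this correction missed therefore stays open. A linked segment from mice of another genetic background would place called genes in blocks. The share with a called neighbour in the same direction within 1 Mb was 1.06 times that of permuted calls (44.8% against 42.3%, 38.7% to 46.1%, one-sided permutation p = 0.106 over 1000 permutations). No clear excess of such blocks was thus seen. A background that differs along the whole genome need not form blocks, so this test cannot speak to it and it stays open. The freezing protocol remains a hypothesis, and a separate day of preparation or sequencing of that group, for which the labels give no information, stays open and untested beside it.

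The second pattern is the joint rise of the ribosomal, respiratory chain, mitochondrial ribosomal and proteasome genes in cryopreservation-2, 260 genes with a median log2 fold change of 1.17. A single library does not account for it, since the median stayed between 1.06 (without fresh replicate 3) and 1.33 when each of the 6 libraries was left out. Better recovery of short transcripts may explain a part, because genes matched on length, GC content and expression had a median of 0.41. Only 2.5% of 1000 matched sets had a median above 0.56, and the 260 genes kept a median of 0.862 after the correction for GC content and length. However, the matched genes were longer (1466 against 1123.5 bases), so whether length explains the whole rise cannot be decided from them. An earlier stage of maturation, in which stored mRNAs of the translation machinery keep longer poly(A) tails and those polyadenylated during maturation are recovered less well, predicts lower values of the latter. For 11 such mRNAs the median was -0.534 (10 negative, 0 called) and still -0.502 after the correction for GC content and length, but random lists matched on length, GC content and expression had a median of -0.34 and 5.29% of 10000 were as low, so this explanation stays open with so few genes. Several of these mRNAs are also members of the cell cycle list already seen to be lower, so the test in part reuses that result.

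Other splits of the same samples were counted for each result. Groups of 3 against 3 libraries give 10 splits, too few for a share under 0.05. Between cryopreservation-2 and fresh the real split called 944 genes and the highest other split 1 (1 of 10 splits as large), between cryopreservation-2 and cryopreservation-1 483 and 0 (1 of 10), and between cryopreservation-1 and fresh 0 and 1 (10 of 10). For the F test over 3 groups only 100 of the possible splits were run, drawn at random beside the real one. Of these 100, 2 called as many, the real one with 619 genes included. That share is under 0.05, which makes a random grouping an unlikely source of the count but does not exclude it. Nor can the count be told from a batch shared by the cryopreservation-2 libraries. The count shows only that cryopreservation-2 stands apart, because 5 other splits among those run kept its 3 libraries together and called 1072, 597, 474, 355 and 336 genes, and the rest of those run called at most 1. The split with 1072 joined fresh replicates 1 and 3 with cryopreservation-1 replicate 3 and fresh replicate 2 with cryopreservation-1 replicates 1 and 2. A direct comparison of those 6 samples divided in the same way called 0 genes, so the larger count does not by itself show a structure among them.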

How the results depend on the processing

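All settings were planned except the thinning, the correction for GC content and length, protein-coding genes alone, upper-quartile scaling and the edgeR filter on mean FPKM, which were chosen after the data were seen. Of the named genes' values under the alternatives, 4594 kept their side of the threshold, 531 no longer passed and 9 newly passed. A change of direction was counted only where the main or the alternative value passed, and 0 were found. For the lists, by camera's direction, the counts were 2968, 43, 73 and 0. Changes of sign between values that both did not pass were counted as kept. Named genes were lost most often without cryopreservation-1 replicate 1 (65), and of the lists cholesterol synthesis between the methods most often, in 17 of 32 alternatives, most of them limma on FPKM. Counts of calls moved more, and the cause was not tested except that fewer samples entered the fits without a library or with 2 groups. With DESeq2 the counts were 43 (cryopreservation-1 against fresh), 2447 (cryopreservation-2 against fresh), 1868 (between the methods) and 2218 (all 3 groups). Fits of only the 2 groups gave 1 and 429 against fresh, and with limma on FPKM 1 for cryopreservation-1 and 1196 between the methods. For cryopreservation-2 against fresh, limma on log2(FPKM + 1) called 1688, with pseudocounts of 0.1 and 5 1597 and 1693, with median-ratio scaling 1704, quantile normalization 1662, no trend 1681, robust fitting 1659 and array weights 2354. Between the methods these were 1271, 1077, 1359, 1278, 1336, 1255, 1247 and 2450, and over all groups 1327, 1224, 1380, 1359, 1382, 1319, 1311 and 2449. Limma without a filter called 882 between the methods and 931 over all groups, and 858 between the methods with a minimum mean FPKM of 5. The correction for GC content and length gave 1491, 1003 and 1085, and the edgeR filter on mean FPKM 955 between the methods and 1095 over all groups. Without 1 library at a time the counts ranged from 0 to 1 for cryopreservation-1 against fresh, from 231 to 786 for cryopreservation-2 against fresh, from 15 to 480 between the methods and from 116 to 469 over all groups.

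Lists called numbered 2, 5 and 6 in the order cryopreservation-1 against fresh, cryopreservation-2 against fresh and between the methods. With an estimated correlation they were 0, 0 and 0, and with fry, which asks whether a list moves one way and does not compare it with other genes, 0, 8 and 7. For cryopreservation-1, 4 lists were called with limma on log2(FPKM + 1), quantile normalization, no trend, robust fitting, array weights, the limma block and the edgeR filter on mean FPKM, 5 with a pseudocount of 0.1 or no filter, and 1 after the correction for GC content and length. For cryopreservation-2 against fresh 10 were called without a low-count filter, and between the methods 3 with limma at a minimum mean FPKM of 5. Without 1 library at a time the lists called ranged from 1 to 6, from 5 to 9 and from 6 to 8. The correlation of the methods' changes, 0.508 over all tested genes and 0.348 over genes with a mean FPKM of at least 1, was 0.326 with limma on log2(FPKM + 1), 0.351 with a pseudocount of 0.1 and 0.341 with median-ratio scaling over the latter genes, and 0.325 at a minimum mean FPKM of 5.

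The groups share replicate numbers, but the correlations of the deviations of same-numbered samples from their group means were not all over 0.1 in any comparison, so the numbers were not taken as pairs. They were 0.072, 0.079 and 0.122 between cryopreservation-1 and fresh, -0.070, 0.059 and -0.089 between cryopreservation-2 and fresh, and -0.125, 0.022 and -0.080 between the methods. In these deviations each cryopreservation-1 library correlated best with the fresh library of its own number, which is a hint from the data and not from the design, and the other comparisons did not show this. With a replicate block edgeR called 0, 500, 230 and, over all groups, 282 genes, and limma on FPKM 958 between the methods and 1098 over all groups. Depth limits mainly genes near the filter, as a count of 0 allows up to 0.0608 CPM in the smallest library.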

Other observations

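The enrichment tests and the count of genes silent in fresh oocytes were chosen after the data were seen, and so were the genes named in this part. Genes of the dynein motor, which carries cargo along microtubules, were enriched among those higher in cryopreservation-2 than in fresh oocytes. Of 24 tested genes of the cytoplasmic dynein complex, 9 were called higher against 0.86 expected (one-sided Fisher's exact test, adjusted p = 2.88e-05). Among them the light chain Dynll1 rose from 6.91 ± 2.66 to 40.2 ± 17.6 CPM (SD, n = 3, edgeR adjusted p = 0.00997), the roadblock-type chain Dynlrb1 3.59-fold and the dynein-associated Wdr60 4.83-fold. Dync1i1, an intermediate chain, had a mean of 0 CPM in fresh and in cryopreservation-1 and 3.74 ± 2.31 CPM in cryopreservation-2. Dynlt1a, Dynlt1b, Dynlt1c and Dynlt1f, also in the term, are near-identical copies that can share reads, so the count of 9 can overstate the number of separate genes. Between the methods, 7 of the 24 were called higher (adjusted p = 1.16e-04). The enrichment tests in this part treat genes as independent and did not match them on transcript length. Genes called higher against fresh had a median length of 1588 bases, against 2548 for all tested genes. Whether short transcripts account for an enrichment was not tested.

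Genes of microtubule-based processes were enriched as well, with 8 of 33 tested genes called higher against 1.18 expected (adjusted p = 0.00299). Among them were Tubb2a, at 110 ± 24.9 against 23.7 ± 3.07 CPM, Tubb2b at 4.31-fold, Tubb6 at 2.43-fold, Tubb4b at 2.38-fold and the kinesin Kif17 at 2.20-fold, and the tubulin levels can include reads shared between copies. The V-type proton pump gene Atp6v1f rose 2.96-fold, the mitochondrial pore regulator Ppif 4.30-fold and the glutathione peroxidase Gpx1 2.35-fold. In all, 37 of 3143 terms were enriched among 479 genes higher in cryopreservation-2 than in fresh, most of them of the ribosome, respiratory chain, ATP synthase and proteasome, and 18 among 226 genes higher than in cryopreservation-1. Among 334 and 189 lower genes 0 terms were enriched.

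A negative result concerns genes silent in fresh oocytes. Trmu, Atf3, Alkbh4, 1700029F12Rik and Gm4926 had 0 counts in all 3 fresh libraries and at least 10 in each of the 6 cryopreserved ones, with 12 to 67 for Atf3. Chance can account for this pattern, since 16 of the 84 choices of 3 libraries from the 9 gave 5 or more such genes. The highest other number was 25, for fresh replicate 3, cryopreservation-1 replicate 3 and cryopreservation-2 replicate 1, the 3 libraries low on the second principal component.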
